A study of Mus musculus with 35 samples.

How the data were processed

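The measurements were RNA-seq profiles of microglia sorted from the brains of female mice, 1 library per mouse, 35 libraries in 6 groups. Per the labels' protocols, mice were perfused, whole brains were dissociated in a Dounce homogeniser, myelin was removed on Percoll, and live cells were sorted by CD11b and CD45. Between 10000 and 30000 cells were sorted per mouse, and RNA from the equivalent of 2500 to 5000 cells went into SMART-Seq v4 amplification and Nextera XT libraries, per the labels. WT mice carried floxed Tbk1 and no Cre. HET mice carried 1 floxed and 1 normal allele with Cx3cr1-Cre, and KO mice carried 2 floxed alleles with Cx3cr1-Cre. Both HET and KO therefore carried the Cre and WT did not, so only KO against HET was matched for the Cre. The labels named no sequencing or library batch, but the library numbers in them ran in separate ranges for the 4-month and the 22-month mice. Any batch that followed age cannot be told apart from age.

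The authors deposited 1 table of TPM values, transcript abundances scaled to gene length and library total, for 35175 genes. The submitters' processing notes name FastQC, Trimmomatic, DRAGEN and Picard, and per the same notes the build was mm10. Versions and settings of these tools were not given in the sources used here. TPM keeps no read depth, so the depth of each library is unknown, and no counting interval or detection floor was computed. No column of the table was left unused. In 12 rows the gene description held extra semicolons, the table's separator, so values were read from the end of the row.

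TPM values were analysed as log2(TPM + 1), with no further scaling. Genes with a TPM of at least 1 in at least 5 libraries, the size of the smallest groups, were kept, which left 15378 genes, of which 15037 (97.8%) were matched by symbol to a position in the GENCODE annotation of the same mouse assembly. A linear model of the 6 group means was fitted to all 35 libraries with limma 3.58.1 in R 4.3.3 (limma-trend, moderated two-sided tests), and 11 contrasts were tested. These were KO against WT, HET against WT and KO against HET at each age, 22 against 4 months in each genotype, and the differences of the KO and HET effects between ages (interactions). A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 over all genes kept. Fold changes are differences on the log2(TPM + 1) scale, which understates the change of genes with low TPM. Errors of fold changes are standard errors (SE), and errors of group means are SDs between mice. Gene-level TPM for Tbk1 may include exons outside the deleted part. Genes that share reads with near-identical copies, such as H2-Q6 with H2-Q7 and Rpsa with its processed copies, have uncertain separate values, and overlapping or antisense genes cannot be told apart without strand.

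The groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule took Tbk1 and Cx3cr1 in every genotype comparison. It took the 10 largest rises and 10 largest falls among called genes with a mean TPM of at least 5 over the groups compared for KO against WT at each age and for ageing in WT, and 5 of each elsewhere. Predicted genes, clone names, mitochondrial and small RNA genes and pseudogenes were passed over. From each gene list it took up to 4 called members with the smallest adjusted p, or the 2 with the highest TPM where fewer than 2 were called, and from each interaction the 5 genes with the smallest adjusted p. Genes named outside the rule are said to have been chosen after their values were seen.

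Of 30 gene lists, 19 held microglial states and cell functions and 11 held markers of other cell types. Of these lists, 28 had enough members among the genes kept to be tested. The functional lists were homeostatic microglia, disease-associated microglia, interferon-stimulated genes, NF-kB and inflammatory cytokines, MHC class I presentation, MHC class II presentation, autophagy machinery, lysosome, TBK1-STING-TLR signalling, RIPK1 and cell death, proliferation, immediate early and dissociation response, cholesterol synthesis, lipid efflux and storage, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, complement and phagocytosis, and senescence. The marker lists were border-associated macrophages, monocytes, neutrophils, T and NK cells, B cells, astrocytes, neurons, oligodendrocytes, endothelial cells, pericytes and mural cells, and erythroid cells. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with a correlation estimated from the libraries. Members were also counted after adjustment over the list alone.

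Ageing scores were the mean log2(TPM + 1) of the genes called higher at 22 months in 1 genotype minus that of the genes called lower. They were compared between 4-month groups by two-sided exact permutation tests, with genes chosen in libraries outside the groups compared wherever possible. The score from the KO ageing genes was added after the data were seen.

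The steps were tested on simulated data with known changes in a part of these genes and with these group sizes. The rates below hold for the genes changed there and for the spread simulated. Recovery among genes with low TPM, and false calls where genes vary together across libraries, were not measured. For KO against WT at 4 months, over 15378 genes, 47 of 58 genes changed 1.5-fold, 70 of 72 changed 2-fold and 69 of 70 changed 4-fold were recovered, with 12 false calls. For KO against WT at 22 months, over 15378 genes, 41 of 52, 71 of 72 and 76 of 76 were recovered, with 12 false calls. For ageing in WT, over 15378 genes, 46 of 67, 67 of 71 and 61 of 62 were recovered, with 6 false calls.

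The alternatives were a pseudocount of 0.1, no filter, a mean TPM of at least 5, quantile normalization, median-of-ratios scaling, a fit on the groups compared only, library quality weights, a replicate block, a dissociation score as covariate, and leaving out each library in turn. A neutrophil marker score as covariate and leaving out the libraries with S100a9 above 5000 TPM were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.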

Results

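Microglia, the resident macrophages of the brain, were profiled in mice whose microglia had lost 0, 1 or 2 alleles of Tbk1, a kinase of innate immune signalling and autophagy. The groups at 4 months held 6 WT, 5 HET and 5 KO mice, and those at 22 months held 7 WT, 6 HET and 6 KO mice. A mean of 13073 ± 206 genes (SD, n = 6) reached a TPM of 1 in WT at 4 months and 13922 ± 285 (n = 7) in WT at 22 months. The corresponding values were 13549 ± 286 and 14075 ± 216 in HET, and 13193 ± 152 and 13967 ± 258 in KO. The correlation between any 2 libraries across genes lay between 0.948 and 0.986. Read depth is unknown for these TPM values. S100a9, an abundant neutrophil transcript, varied between 323 and 18289 TPM across libraries, with group means of 1564 TPM in WT at 4 months and 6427 TPM in WT at 22 months.

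The targeted gene was examined first. Tbk1 (chromosome 10, 121546455 to 121586787, minus strand, mm10) stood at 69.6 ± 7.20 TPM (SD, n = 6) in WT, 45.7 ± 7.86 (n = 5) in HET and 24.7 ± 4.38 (n = 5) in KO at 4 months. At 22 months it stood at 69.3 ± 7.15 (n = 7), 46.9 ± 2.76 (n = 6) and 31.8 ± 6.18 TPM (n = 6). No KO library overlapped a HET or WT library of its age, and no HET library overlapped WT. In KO against WT, Tbk1 fell by 1.47 on the log2 scale (SE 0.12, limma adjusted p = 4.2e-11) at 4 months and by 1.12 (SE 0.11, adjusted p = 6.4e-09) at 22 months. KO also lay below HET, by log2 -0.86 (SE 0.12, adjusted p = 1.9e-05) at 4 months and -0.57 (SE 0.11, adjusted p = 0.00358) at 22 months. The 22-month call of KO against HET was lost without the libraries with S100a9 above 5000 TPM, a limit set after the data were seen. The HET difference from WT was log2 -0.61 (SE 0.12, adjusted p = 0.0292) at 4 months and -0.55 (SE 0.11, adjusted p = 0.0242) at 22 months. This HET call was lost in 7 of 11 fits at 4 months, those without HET replicate 1, 2, 3 or 4 or WT replicate 2, 3 or 6 (highest adjusted p = 0.122, without HET replicate 4). It was lost in 8 of 13 fits at 22 months, those without HET replicate 2, 3, 4, 5 or 6 or WT replicate 1, 2 or 6 (highest adjusted p = 0.118, without HET replicate 5). The size of the fall stayed between -0.70 and -0.54 at 4 months and between -0.58 and -0.51 at 22 months. Cx3cr1, the fractalkine receptor whose locus drives the Cre, was not called in any genotype comparison. KO against WT gave log2 -0.08 (SE 0.09, adjusted p = 0.944) and 0.07 (SE 0.09, adjusted p = 0.896) at 4 and 22 months. HET against WT gave -0.08 (adjusted p = 0.775) and -0.05 (adjusted p = 0.962). KO against HET gave 0.00 (adjusted p = 1) and 0.12 (adjusted p = 0.787).

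**Figure D1:**
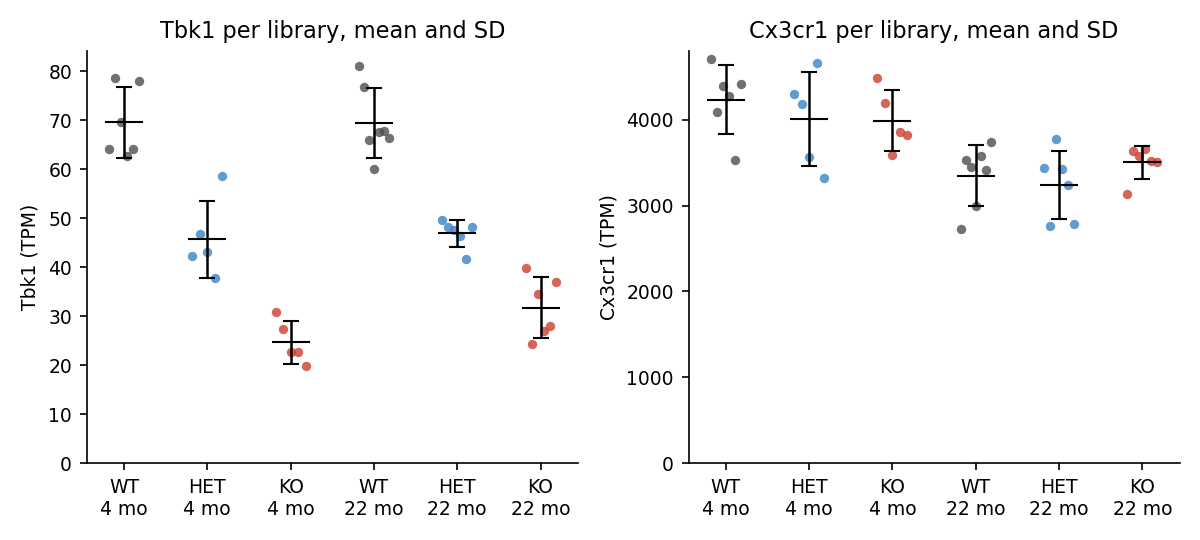
TPM of Tbk1 and Cx3cr1 in each library by genotype and age, with group means and SDs. Mean Tbk1 fell from 69.6 in WT to 24.7 TPM in KO at 4 months and from 69.3 to 31.8 TPM at 22 months, while Cx3cr1 group means lay between 3238 and 4232 TPM.

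Loss of both alleles in young mice was addressed by KO against WT at 4 months. Each rise named in this paragraph was seen in all 5 KO libraries, without overlap with WT. Cxcl13, a chemokine that attracts B cells, averaged 41.04 ± 28.3 TPM (SD, n = 5) in KO and 0.354 ± 0.335 (n = 6) in WT, a log2 rise of 4.71 (SE 0.43, adjusted p = 1.4e-09). Vcam1, a leukocyte adhesion molecule, rose from 8.997 ± 1.39 to 76.7 ± 16.6 TPM (log2 2.95, SE 0.14, adjusted p = 4.9e-17). Cxcl10, an interferon-induced chemokine, rose from 7.13 ± 2.27 to 68.6 ± 28.5 TPM (log2 3.07, SE 0.31, adjusted p = 1.6e-08). The nuclear receptor gene Rxrg rose by 3.07 (SE 0.19, adjusted p = 5.4e-14), the costimulatory receptor Cd40 by 2.12 (SE 0.30, adjusted p = 1.5e-05) and the cytokine receptor chain Il2rg by 2.02 (SE 0.14, adjusted p = 6.1e-13). Ly6i rose by 2.00 (SE 0.32, adjusted p = 1.0e-04) and the receptor tyrosine kinase Axl by 1.91 (SE 0.17, adjusted p = 1.4e-09). The class I genes H2-Q6 and H2-Q7, whose reads are hard to separate, rose by 2.51 (SE 0.18) and 2.39 (SE 0.22). After Tbk1, the largest falls among genes with a mean TPM of at least 5 were in Slc5a10 (log2 -1.14, adjusted p = 0.00137), Nbl1 (-1.11, adjusted p = 2.2e-04), the protease gene Htra3 (-1.03, adjusted p = 1.3e-04), Ccdc162 (-0.84, adjusted p = 0.0300) and Gpd1 (-0.83, adjusted p = 4.2e-04), with 0 of 5 KO libraries above the WT median. Gas6, a ligand of Axl, fell from 202 ± 17.7 to 122 ± 11.7 TPM (log2 -0.72, SE 0.10, adjusted p = 5.85e-06). The falls in Ccdc162, Asb10 (-0.61) and Sh3bp5 (-0.57) lost their calls in 9, 5 and 10 of 11 fits that left out 1 library. Their highest adjusted p were 0.139 (without KO replicate 3), 0.0840 (without KO replicate 5) and 0.248 (without KO replicate 5).

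Of the interferon-stimulated genes, 15 of 39 rose in KO at 4 months and 0 fell, and 32 rose when adjusted over the list alone (median log2 0.76, camera adjusted p = 9.0e-54, adjusted p = 2.6e-04 with an estimated correlation). Examples were Oas1a (log2 1.21, SE 0.17), an antiviral RNA sensor, Usp18 (1.07, SE 0.17) and Lgals3bp (0.89, SE 0.14). NF-kB and inflammatory cytokine genes rose in 14 of 29 members, and adjusted over the list alone 19 rose and 1 fell (median 0.53, adjusted p = 3.5e-43, adjusted p = 1.6e-08 with an estimated correlation). Il12b, a subunit of interleukin-12, rose by 1.83 (SE 0.22, adjusted p = 5.1e-07), the chemokine Ccl2 by 1.68 (SE 0.22), Cxcl16 by 1.07 (SE 0.09) and the receptor Tlr2 by 0.79 (SE 0.10). MHC class I genes rose in 9 of 16 members (12 adjusted over the list alone, median 0.48, adjusted p = 5.5e-39, adjusted p = 4.5e-05 with an estimated correlation), among them H2-K1 (1.09, SE 0.10), H2-D1 (1.00, SE 0.10) and B2m (0.55, SE 0.09). Disease-associated microglia genes had 5 rises and 2 falls among 28 (8 and 2 adjusted over the list alone, median 0.24, adjusted p = 1.0e-11, adjusted p = 0.0154 with an estimated correlation), with rises in Cst7 (1.27, SE 0.17) and Itgax (1.15, SE 0.16).

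Other lists passed camera in KO at 4 months only with the preset correlation. Homeostatic microglia genes had 2 falls among 28 (4 adjusted over the list alone, median -0.17, adjusted p = 7.4e-09, adjusted p = 0.229 with an estimated correlation). These were Fcrls (log2 -0.47, adjusted p = 0.00502) and Slc2a5 (-0.46, adjusted p = 0.0107, 0.0564 without KO replicate 5). MHC class II (1 rise among 12, H2-Oa, log2 0.62, median 0.14, adjusted p = 2.2e-04), lysosome (0 of 33 called, median 0.06, adjusted p = 2.9e-04), ribosomal protein (median 0.07, adjusted p = 0.00128) and proliferation genes (median 0.35, adjusted p = 8.0e-06) leaned higher. None of the 4 held, with adjusted p = 0.198, 0.533, 0.580 and 0.252 with an estimated correlation. Autophagy genes (0 of 28 called, median -0.10, adjusted p = 0.00347) and border-associated macrophage markers (0 of 12 called, median -0.50, adjusted p = 4.6e-04) leaned lower. Neither held, with adjusted p = 0.234 and 0.229 with an estimated correlation. Complement genes (median 0.05, adjusted p = 0.00605) and senescence genes (median 0.07, adjusted p = 0.00736) gave adjusted p = 0.261 and 0.114 with an estimated correlation. The senescence gene Cdkn1a, a cell cycle inhibitor, rose by 0.75 (SE 0.12, adjusted p = 1.7e-04). In the TBK1-STING-TLR list, Tank, an adaptor that binds TBK1, rose by 0.87 (SE 0.10, adjusted p = 2.6e-07), and the list did not pass (median -0.05, mean 0.03, adjusted p = 0.681).

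The remaining lists did not pass at 4 months: RIPK1 and cell death (median -0.03, mean 0.01, adjusted p = 0.582), immediate early (median 0.04, adjusted p = 0.349), cholesterol synthesis (median 0.03, adjusted p = 0.098) and lipid efflux (median 0.15, adjusted p = 0.098). Neither did glycolysis (median -0.01, mean 0.03, adjusted p = 0.563) or oxidative phosphorylation (median 0.01, adjusted p = 0.586). Markers of monocytes (median 0.45, adjusted p = 0.104), neutrophils (median 0.50, adjusted p = 0.106), and T and NK cells (median 0.36, adjusted p = 0.087) did not pass. With a pseudocount of 0.1 the T and NK cell list passed camera as higher (adjusted p = 0.0478). The same held for B cells (median 0.05, adjusted p = 0.679), astrocytes (median 0.03, adjusted p = 0.332), oligodendrocytes (median 0.04, adjusted p = 0.679), endothelial cells (median -0.07, adjusted p = 0.238) and erythroid cells (median -1.08, adjusted p = 0.278). No marker of neurons or of pericytes and mural cells was among the genes kept. In total 136 genes rose and 23 fell in KO at 4 months, 53 and 4 of them by more than 2-fold. The count of 159 became 282 with library quality weights (216 higher and 66 lower) and 113 without KO replicate 5.

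KO was also compared with WT in aged mice, and each rise named in this paragraph was seen in all 6 KO libraries and, except for Mt2, without overlap with WT. Cxcl13 rose from 17.1 ± 12.3 TPM (SD, n = 7) to 263 ± 99.9 (n = 6), a log2 rise of 4.00 (SE 0.39, adjusted p = 1.6e-08), and Vcam1 from 30.4 ± 6.12 to 138 ± 19.2 TPM (2.16, SE 0.13, adjusted p = 5.9e-14). Madcam1, another adhesion molecule, rose by 2.76 (SE 0.30, adjusted p = 1.6e-07), Cxcl10 by 2.15 (SE 0.29, adjusted p = 5.8e-06), and Rxrg by 2.11 (SE 0.17, adjusted p = 2.0e-10). H2-Q6 rose by 1.68, H2-Q7 by 1.66, the metallothionein Mt2 by 1.63 (adjusted p = 4.6e-04), Cd40 by 1.53 (adjusted p = 7.4e-04) and Cd69 by 1.47 (adjusted p = 5.6e-04). Among genes with a mean TPM of at least 5, the largest falls were in Pf4 and Cbr2, markers of border-associated macrophages, which line the brain's vessels and meninges. Pf4 fell by 1.77 (SE 0.37, adjusted p = 0.00554, 37.4 ± 23.4 to 8.83 ± 2.55 TPM) and Cbr2 by 1.60 (SE 0.32, adjusted p = 0.00248), with 0 of 6 KO libraries above the WT median. Fndc4 (-1.25, adjusted p = 5.9e-05), Emp2 (-1.03, adjusted p = 0.00119), Htra3 (-0.91, adjusted p = 3.0e-04), the phosphate transporter gene Ank (-0.90, adjusted p = 1.4e-06) and Rab7b (-0.85, adjusted p = 0.00882) also fell. The falls in Mrc1 (-0.96, adjusted p = 0.0255), the mannose receptor, and Dab2 (-0.88, adjusted p = 0.0109) lost their calls in 7 and 1 of 13 fits leaving out 1 library. The highest adjusted p were 0.0842 (without WT replicate 2) and 0.0557 (without KO replicate 2).

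NF-kB and inflammatory cytokine genes rose in 14 of 29 members at 22 months (18 rose and 1 fell adjusted over the list alone, median 0.55, adjusted p = 4.4e-27, adjusted p = 1.8e-06 with an estimated correlation), led by Il12b (log2 2.68, SE 0.20, adjusted p = 1.8e-11), Tnip1 (0.84, SE 0.11) and Cxcl16 (0.80, SE 0.08). MHC class I genes rose in 7 of 16 (11 adjusted over the list alone, median 0.45, adjusted p = 1.0e-25, adjusted p = 9.3e-04 with an estimated correlation), with H2-K1 at 0.83 and H2-D1 at 0.63. Interferon-stimulated genes rose in 7 of 39 (20 adjusted over the list alone, median 0.37, adjusted p = 1.5e-24, adjusted p = 0.0179 with an estimated correlation), with Mx1 at 0.94 (SE 0.14) and Ifit3 at 0.88 (SE 0.18). Border-associated macrophage markers fell in 6 of 12 (10 adjusted over the list alone, median -0.96, adjusted p = 5.3e-18, adjusted p = 9.96e-04 with an estimated correlation), among them the scavenger receptor Cd163 (-1.87, SE 0.26, adjusted p = 1.2e-05) and Cd209f (-1.93, SE 0.38). Monocyte (median -0.13, adjusted p = 0.501), neutrophil (median -0.07, mean 0.03, adjusted p = 0.988), T and NK cell (median 0.22, adjusted p = 0.513) and B cell markers (median 0.28, adjusted p = 0.268) did not pass. Disease-associated microglia genes (2 up, 1 down, median -0.05, adjusted p = 0.870), homeostatic genes (2 down, median -0.04, adjusted p = 0.106) and MHC class II genes (1 up, median 0.05, mean -0.10, adjusted p = 0.870) did not pass as lists. Lysosome (median 0.07, adjusted p = 9.1e-04), cholesterol (median 0.12, adjusted p = 0.0202) and erythroid lists (median 1.93, adjusted p = 0.0202) passed only with the preset correlation (adjusted p = 0.723, 0.598 and 0.598 with an estimated correlation). In total 130 genes rose and 55 fell, 36 and 12 by more than 2-fold. With the neutrophil score as covariate in all libraries, a setting added after the data were seen, 230 genes were called. Without the libraries with S100a9 above 5000 TPM, 4 of 7 WT and 3 of 6 KO, 84 genes were called. This limit was also set after the data were seen. Without these libraries homeostatic (adjusted p = 2.7e-05), glycolysis (2.3e-06), lipid efflux (6.4e-04) and autophagy lists (0.0241) passed as lower with the preset correlation. The ribosomal protein list (0.00545) passed as higher, and lysosome (0.919) and erythroid lists (0.188) no longer passed.

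Both ages shared 76 rises (1.15 in independent lists) and 10 falls (0.0823), from comparisons with no library in common. Of the 159 genes called at 4 months, 156 had the same sign at 22 months, and the fold changes of these genes correlated at r = 0.876 (0.348 over all genes). Genes are not independent replicates. The test of the difference between ages called 0 genes with limma (544 at unadjusted p below 0.05, lowest adjusted p = 0.106), and 0 to 3 when 1 library was left out. It called 3 without KO replicate 4 at 4 months, and 2 without KO replicate 2 or WT replicate 6 at 4 months. With library quality weights it called 3 genes, and in the other planned settings 0. The smallest adjusted p, 0.106, belonged to Ch25h (log2 -1.92, SE 0.37), Axl (-1.17, SE 0.24) and Il2rg (-0.92, SE 0.18), followed by Ccl4 (-1.03, adjusted p = 0.341) and Lox (-1.33, adjusted p = 0.374). As a list, disease-associated microglia genes differed between ages (median -0.37, camera adjusted p = 9.4e-13, adjusted p = 0.0330 with an estimated correlation): the KO effect was more negative at 22 months, and 6 members were lower adjusted over the list alone.

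**Figure D2:**
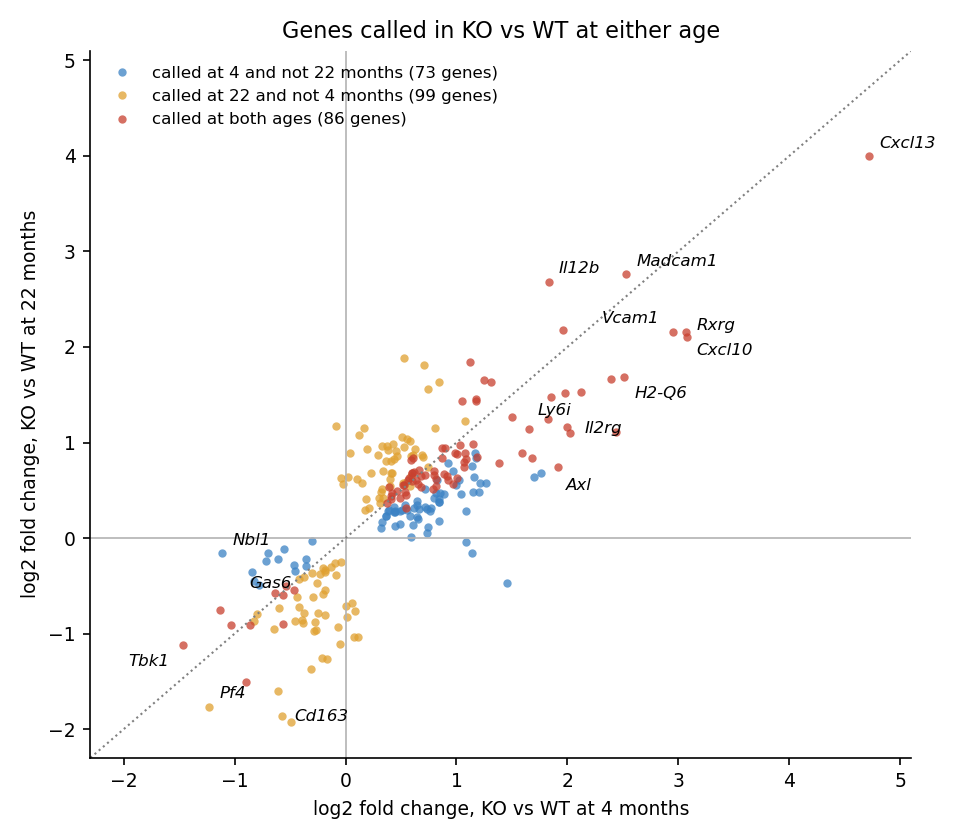
Log2 fold changes of KO against WT at 4 months (x axis) and at 22 months (y axis) for genes called at either age, 1 point per gene. Of these genes 86 were called at both ages, 73 at 4 months and not at 22, and 99 at 22 months and not at 4, and Cxcl13 lay highest at both (4.71 and 4.00).

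Loss of 1 allele was addressed by HET against WT. At 4 months Slc25a38, a mitochondrial carrier gene, rose from 35.1 ± 2.17 TPM (SD, n = 6) to 68.0 ± 11.7 (n = 5), a log2 rise of 0.92 (SE 0.11, adjusted p = 1.8e-05). Rpsa, a ribosomal protein gene with near-identical copies, rose from 98.2 ± 11.3 to 148 ± 13.8 TPM (0.59, SE 0.08, adjusted p = 7.3e-05). At 22 months they rose by 0.69 (SE 0.10, adjusted p = 4.3e-04) and 0.68 (SE 0.07, adjusted p = 7.0e-07), and at both ages all HET libraries lay above all WT libraries. In KO against WT, values chosen after they were seen, Slc25a38 rose by 0.59 (adjusted p = 0.00136) and 0.82 (adjusted p = 2.1e-06) and Rpsa by 0.64 and 0.61. Both genes lie on chromosome 9 beside Cx3cr1 (119901616 to 120069879): Slc25a38 at 120110374 to 120124504 and Rpsa at 120127689 to 120132369. The other calls at 4 months were Tbk1, Lcmt1 (-0.60, adjusted p = 0.0292) and, chosen after the values were seen, the copy Rpsa-ps10 (0.53). Lcmt1 lost its call in 6 of 11 fits leaving out 1 library (highest adjusted p = 0.166, without HET replicate 5). At 22 months they were Tbk1 and, chosen after the values were seen, Rpsa-ps10 (0.65), Gm23262 (1.59) and Ephb6 (-1.16).

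In total 5 genes were called in HET at 4 months (3 higher, 2 lower, 1640 at unadjusted p below 0.05) and 6 at 22 months (4 higher and 2 lower, 850 at unadjusted p below 0.05). The 4-month count was 2 without HET replicate 2 or 3 or WT replicate 3, and 3 without HET replicate 4 or 5 or WT replicate 2 or 6. It was 1 in a fit on these groups only, and 3 without the libraries with S100a9 above 5000 TPM. At 4 months interferon-stimulated genes leaned higher (median 0.24, camera adjusted p = 3.0e-04). The homeostatic (median -0.12, adjusted p = 2.3e-06), lysosome (median -0.10, adjusted p = 2.3e-06), autophagy (median -0.05, adjusted p = 0.00574) and erythroid lists (median -2.08, adjusted p = 0.00550) leaned lower, and no member of these 5 lists was called. None held, with adjusted p = 0.931, 0.749, 0.794, 0.749 and 0.749 with an estimated correlation. At 22 months interferon-stimulated (median 0.14, adjusted p = 0.0130), ribosomal protein (median 0.11, adjusted p = 9.1e-05) and erythroid genes (median 1.59, adjusted p = 0.0243) leaned higher. The homeostatic (median -0.08, adjusted p = 0.00572), glycolysis (median -0.06, adjusted p = 0.0332) and border-associated macrophage lists (median -0.57, adjusted p = 2.3e-07) leaned lower. The macrophage list gave adjusted p = 0.192 with an estimated correlation and the other 5 gave adjusted p = 0.930. The interferon-stimulated list no longer passed without the libraries with S100a9 above 5000 TPM (adjusted p = 0.571). MHC class II (adjusted p = 6.0e-04), lysosome (adjusted p = 1.1e-04), complement (adjusted p = 0.00347), lipid efflux (adjusted p = 0.0172) and B cell lists (adjusted p = 7.1e-04) then passed as lower and proliferation (adjusted p = 3.8e-04) as higher, with the preset correlation. The HET effect differed between ages for 0 genes in limma (587 at unadjusted p below 0.05, lowest adjusted p = 0.271, Gm23262, log2 1.69) and in the other planned settings. It differed for 1 gene without HET replicate 5 at 22 months and for 1 gene without the libraries with S100a9 above 5000 TPM.

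**Figure D3:**
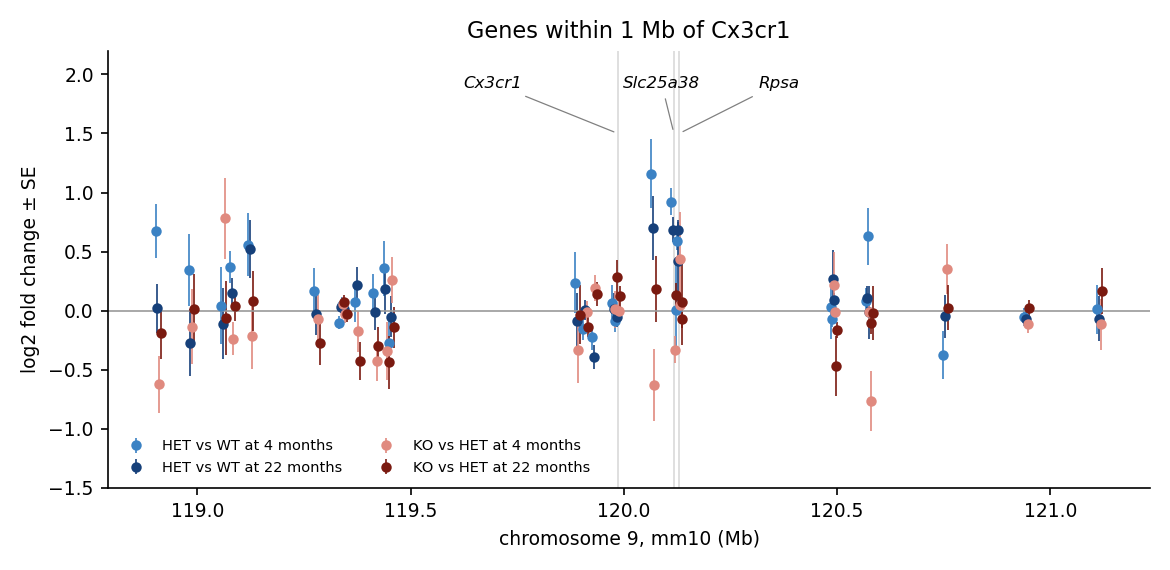
Log2 fold changes with standard errors (y axis) of the genes kept within 1 Mb of Cx3cr1 against position on chromosome 9 (x axis, mm10), for HET against WT and KO against HET at each age, with vertical lines at the 3 named genes. Slc25a38 stood at 0.92 and 0.69 in HET against WT at 4 and 22 months and at -0.33 and 0.13 in KO against HET, and Rpsa at 0.59 and 0.68, then 0.05 and -0.07.

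KO against HET, in which both groups carried the Cre, addressed the second allele. At 4 months Cxcl13 rose from 1.73 ± 1.94 TPM (SD, n = 5) to 41.04 ± 28.3 (n = 5), a log2 rise of 3.97 (SE 0.45, adjusted p = 3.4e-07). Vcam1 rose by 2.78 (SE 0.15, adjusted p = 1.3e-15), Cxcl10 by 2.68 (SE 0.33, adjusted p = 1.4e-06), Rxrg by 2.49 (SE 0.20, adjusted p = 6.8e-11), H2-Q6 by 1.92 and Axl by 1.47 (adjusted p = 1.9e-06). Ccdc162 fell by 1.12 (adjusted p = 0.00276), Csmd3 by 1.01 (adjusted p = 6.2e-04) and Nbl1 by 0.89 (adjusted p = 0.0105). Lgals4 (-0.98) and Adamts10 (-0.91) lost their calls in 4 and 5 of 10 fits leaving out 1 library (highest adjusted p = 0.130 and 0.124, both without HET replicate 5). NF-kB genes rose in 14 of 29 (17 higher and 1 lower adjusted over the list alone, median 0.45, adjusted p = 8.9e-29, adjusted p = 1.1e-06 with an estimated correlation) and MHC class I genes in 7 of 16 (11 adjusted over the list alone, median 0.32, adjusted p = 8.9e-29, adjusted p = 4.0e-04 with an estimated correlation). Interferon-stimulated genes rose in 6 of 39 (22 adjusted over the list alone, median 0.40, adjusted p = 2.6e-24, adjusted p = 0.0249 with an estimated correlation). Senescence genes passed as well (median 0.20, adjusted p = 0.00141, adjusted p = 0.0449 with an estimated correlation) with 0 of 11 called. The other lists that passed did so only with the preset correlation. Disease-associated (4 higher and 1 lower of 28, median 0.14, adjusted p = 1.3e-07), lysosome (2 of 33 higher, median 0.17, adjusted p = 6.7e-14), complement (median 0.11, adjusted p = 8.1e-05) and MHC class II lists (median 0.14, adjusted p = 5.2e-04) leaned higher. They gave adjusted p = 0.0722, 0.134, 0.106 and 0.172 with an estimated correlation. Cholesterol (median 0.15, adjusted p = 0.00403) and proliferation lists (median 0.12, adjusted p = 0.00650) gave adjusted p = 0.238 and 0.615 with an estimated correlation. Border-associated macrophage markers leaned lower (0 of 12 called, median -0.61, adjusted p = 1.4e-04, adjusted p = 0.158 with an estimated correlation). Without the libraries with S100a9 above 5000 TPM, monocyte (adjusted p = 0.0135), immediate early (adjusted p = 0.0101), ribosomal protein (adjusted p = 0.00317) and oxidative phosphorylation lists (adjusted p = 0.0240) passed as higher with the preset correlation. The homeostatic list passed as lower both there (adjusted p = 0.0250) and with quantile normalization of all libraries (adjusted p = 0.00116). Examples of the called genes were Cxcl16 (1.11), Tlr2 (0.85), H2-K1 (0.97) and Tank (0.92). In total 106 genes rose and 55 fell (65.8% higher, 79.9% with quantile normalization and 78.9% with median-of-ratios scaling). The count of 161 became 77 without KO replicate 5, 102 without HET replicate 5, 257 without KO replicate 1, 55 in a fit on these groups only, 99 without a filter and 101 without the libraries with S100a9 above 5000 TPM.

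At 22 months Cxcl13 rose in KO against HET by 3.63 (SE 0.41, adjusted p = 6.2e-07, 20.8 ± 8.07 to 263 ± 99.9 TPM), Cxcl10 by 2.02 (adjusted p = 8.7e-05), Madcam1 by 1.91 (adjusted p = 4.7e-04), and Vcam1 by 1.90 (SE 0.13, adjusted p = 9.3e-12). Rxrg rose by 1.77 (adjusted p = 6.5e-08) and Il12b by 2.84 (adjusted p = 1.1e-11). Htra3 fell by 0.97 (adjusted p = 4.3e-04), Abcg3 by 0.77 (adjusted p = 0.00135) and Ank by 0.70 (adjusted p = 4.9e-04). Lyzl4 (-0.92) and Ramp1 (-0.59) lost their calls in 4 and 2 of 12 fits leaving out 1 library (highest adjusted p = 0.0761, without KO replicate 4, and 0.0733, without HET replicate 5). NF-kB genes rose in 12 of 29 (16 higher and 2 lower adjusted over the list alone, median 0.43, adjusted p = 2.6e-26, adjusted p = 2.4e-06 with an estimated correlation) and MHC class I genes in 6 of 16 (12 adjusted over the list alone, median 0.36, adjusted p = 3.6e-22, adjusted p = 0.00238 with an estimated correlation). Interferon-stimulated genes rose in 3 of 39 (9 adjusted over the list alone, median 0.25, adjusted p = 9.2e-16, adjusted p = 0.128 with an estimated correlation). Of the macrophage markers 1 of 12 fell, Cd163 (-1.30, adjusted p = 0.00839), with 2 lower adjusted over the list alone and a list median of -0.38 (adjusted p = 1.6e-05, adjusted p = 0.176 with an estimated correlation). Lysosome (median 0.09, adjusted p = 3.8e-08), cholesterol (median 0.14, adjusted p = 0.0123) and TBK1-STING-TLR lists (median 0.07, adjusted p = 0.0315) leaned higher, each with adjusted p = 0.420 with an estimated correlation. Ribosomal protein genes leaned lower (median -0.07, adjusted p = 0.0400, adjusted p = 0.994 with an estimated correlation). Without the libraries with S100a9 above 5000 TPM, B cell markers passed as higher (adjusted p = 0.00211), and proliferation (adjusted p = 3.1e-05) and glycolysis lists (adjusted p = 0.00280) as lower, with the preset correlation. The ribosomal protein list no longer passed (adjusted p = 0.510). In total 78 genes rose and 24 fell. With the neutrophil score as covariate in all libraries 134 genes were called. Without the libraries with S100a9 above 5000 TPM, 2 of 6 HET and 3 of 6 KO, 31 genes were called.

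**Figure D4:**
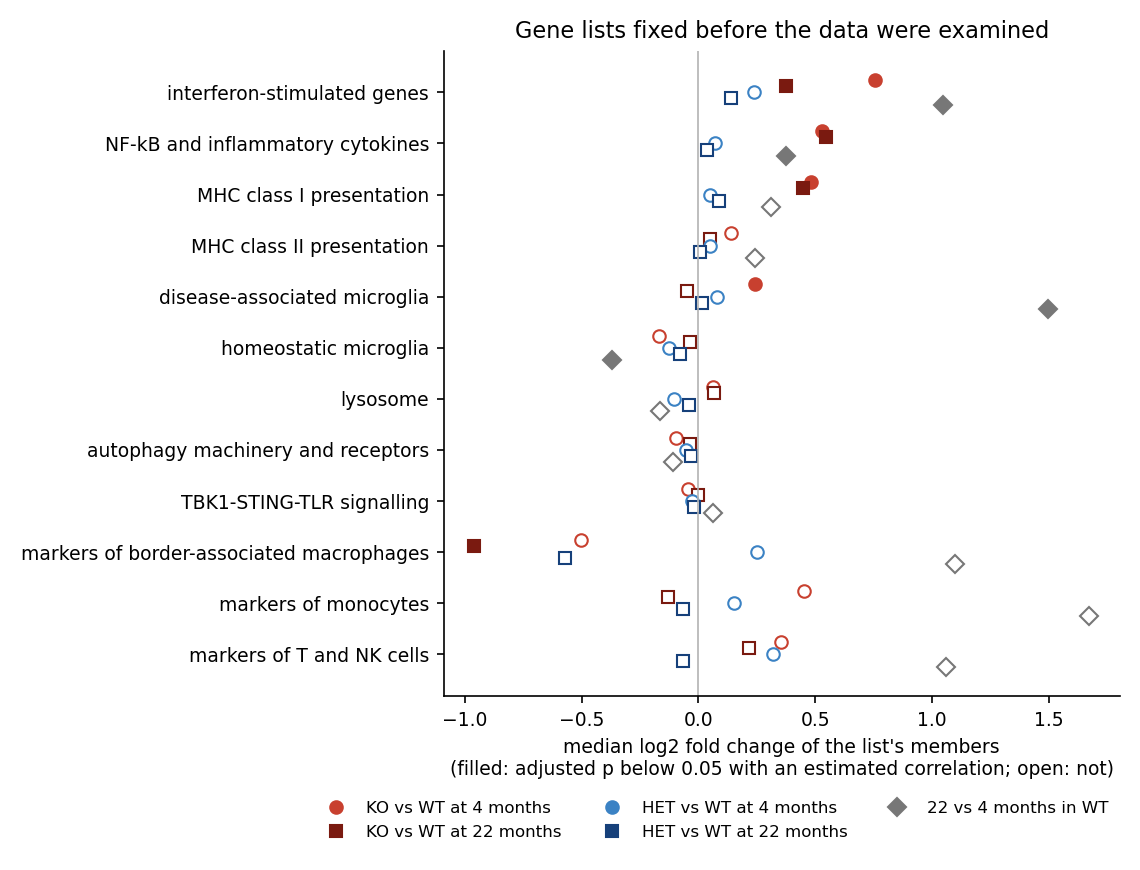
Median log2 fold change of each list's members (x axis) in 5 comparisons, where filled symbols mark adjusted p below 0.05 with an estimated correlation. Interferon-stimulated genes stood at 0.76 and 0.37 in KO at 4 and 22 months and at 1.05 in WT ageing, and border-associated macrophage markers at -0.96 in KO at 22 months.

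Ageing in control mice was addressed by 22 against 4 months in WT, where all 7 aged libraries lay above the young median for each rise named here. Spp1, which encodes osteopontin, rose from 5.09 ± 3.51 TPM (SD, n = 6) to 126 ± 44.3 (n = 7), a log2 rise of 4.47 (SE 0.27, adjusted p = 1.6e-14). Ch25h, the cholesterol 25-hydroxylase, rose by 4.25 (SE 0.25), the elastase Mmp12 by 3.84 (SE 0.23) and Cxcl13 by 3.56 (SE 0.39). Wfdc17 and Lilrb4a rose by 2.91, Hcar2 by 2.68, Clec7a by 2.58 (SE 0.15), Ccl8 by 2.51 and Rxrg by 2.46. Among genes with a mean TPM of at least 5, the largest falls were in P2rx1 (-1.31, adjusted p = 7.9e-06), Il7r (-1.21, adjusted p = 2.3e-04), Pecam1 (-0.999, adjusted p = 5.4e-05), Ptger3 (-0.98), Nid2 (-0.97), Mycl (-0.94), Smim10l2a (-0.92), Tmem204 (-0.91), Gpr165 (-0.89) and Cd276 (-0.81). Age and any batch cannot be told apart here.

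Interferon-stimulated genes rose with age in 38 of 39 members (median 1.05, adjusted p = 4.2e-30, adjusted p = 0.00844 with an estimated correlation), such as Ifi207 (1.89) and Oasl2 (1.72). Disease-associated genes rose in 18 of 28 (median 1.498, adjusted p = 7.3e-17, adjusted p = 0.00844 with an estimated correlation), such as Apoe (2.19, SE 0.14), a lipid carrier, and Lpl (2.42). NF-kB genes had 14 rises and 1 fall among 29 (median 0.37, adjusted p = 5.6e-08, adjusted p = 0.00844 with an estimated correlation), such as Ccl4 (2.39, SE 0.16), Ccl3 (2.30) and Tnf (2.16). Homeostatic genes fell in 23 of 28 (median -0.37, adjusted p = 4.4e-21, adjusted p = 0.0251 with an estimated correlation), such as Fcrls (-0.68) and the purinergic receptor P2ry12 (-0.47). Adjusted over the list alone, the counts were 38 of 39, 18 higher and 2 lower, 14 and 1, and 25 lower.

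The other ageing lists passed only with the preset correlation or not at all. MHC class I (10 of 16 higher, median 0.31, adjusted p = 2.5e-05), MHC class II (6 of 12, median 0.24, adjusted p = 0.00204), ribosomal protein (17 of 30, median 0.28, adjusted p = 2.8e-07), proliferation (7 of 23, median 0.54, adjusted p = 5.8e-04) and lipid efflux lists (6 of 20, with 2 lower, median 0.14, adjusted p = 0.0318) leaned higher. They gave adjusted p = 0.246, 0.252, 0.363, 0.363 and 0.252 with an estimated correlation, and 10, 6, 21, 9 and 7 rises adjusted over the list alone. Lysosome (8 of 33 lower, 1 higher, median -0.16, adjusted p = 3.7e-07) and autophagy genes (5 of 28 lower, median -0.11, adjusted p = 6.5e-04) gave adjusted p = 0.341 and 0.238 with an estimated correlation, and 15 and 5 falls adjusted over the list alone. Beside these gene groups, markers of monocytes (7 of 10 higher, median 1.67, adjusted p = 3.7e-07), border-associated macrophages (7 of 12, median 1.10, adjusted p = 0.00118) and T and NK cells (6 of 8, median 1.06, adjusted p = 0.00399) moved with age. They gave adjusted p = 0.246, 0.252 and 0.363 with an estimated correlation, and 10, 9 and 7 rises adjusted over the list alone. Among them were Ccr2 (2.01, SE 0.28), a monocyte chemokine receptor, Ms4a7 (1.55) and Gzma (1.59). Neutrophil markers had 0 of 11 called (median 0.84, adjusted p = 0.560), with S100a8 at 1.39 (adjusted p = 0.275) and S100a9 at 1.34 (adjusted p = 0.293). Without the libraries with S100a9 above 5000 TPM, proliferation (adjusted p = 0.522) and T and NK cell lists (adjusted p = 0.118) no longer passed.

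In WT 2079 genes rose and 903 fell with age, 425 and 4 of them by more than 2-fold. The share of rises was 69.7%, against 41.9% with quantile normalization, which moved the median of all genes by -0.13, and 52.4% with median-of-ratios scaling. The count was 1382 with a dissociation score as covariate and 2822 with the neutrophil score as covariate. It was 671 without the libraries with S100a9 above 5000 TPM, 4 of 7 aged WT libraries. In HET 757 rose and 384 fell (66.3% higher, 49.3% with quantile normalization), 754 in all without replicate 1 at 4 months and 1567 without replicate 5 at 4 months. The HET count was 374 with the dissociation covariate, 593 in a fit on these groups only and 1910 with library quality weights. In KO 1613 rose and 489 fell (76.7% higher, 44.2% with quantile normalization and 52.4% with median-of-ratios scaling), 1351 in all without replicate 6 at 22 months and 1368 without replicate 5 at 4 months. The KO count was 735 with the dissociation covariate and 1346 without a filter.

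Spp1 (3.78 and 4.04), Ch25h (3.82 and 2.33), Mmp12 (3.43 and 3.14) and Cxcl13 (3.18 and 2.85) were among the largest ageing rises in HET and KO, and Gpr165 fell by 1.02 in each. Of the genes that rose in WT, 612 were also called higher in HET and 1059 in KO, and 1988 and 2044 had the same sign. Interferon-stimulated genes rose in 31 of 39 in HET (median 1.01, adjusted p = 1.1e-33, adjusted p = 0.00472 with an estimated correlation) and 32 of 39 in KO (median 0.85, adjusted p = 9.9e-20, adjusted p = 0.0532 with an estimated correlation). Disease-associated genes rose in 17 of 28 in HET (median 1.18, adjusted p = 3.3e-24, adjusted p = 8.4e-04 with an estimated correlation) and had 16 rises and 1 fall in KO (median 0.90, adjusted p = 1.1e-09, adjusted p = 0.0532 with an estimated correlation). Homeostatic genes fell in 18 of 28 in HET (median -0.34, adjusted p = 3.5e-19, adjusted p = 0.0379 with an estimated correlation) and 13 in KO (median -0.27, adjusted p = 9.6e-14, adjusted p = 0.116 with an estimated correlation). Monocyte markers rose in 7 of 10 in each (medians 1.49 and 1.34, adjusted p = 2.1e-07 and 2.1e-04, adjusted p = 0.185 and 0.552 with an estimated correlation). Immediate early and dissociation genes passed in HET (4 of 21 higher, median 0.45, adjusted p = 4.0e-04, adjusted p = 0.264 with an estimated correlation) and in KO they did not pass (adjusted p = 0.0699). With quantile normalization they passed camera as higher in KO too (adjusted p = 0.00403). T and NK cell markers leaned higher in HET and KO (medians 0.78 and 0.80, adjusted p = 0.0152 and 0.0310, adjusted p = 0.426 and 0.655 with an estimated correlation), and gave adjusted p = 0.242 and 0.255 with the dissociation covariate. NF-kB genes had 11 rises and 1 fall in HET (median 0.30, adjusted p = 1.7e-10, adjusted p = 0.00240 with an estimated correlation) and 14 rises in KO (median 0.32, adjusted p = 3.8e-06, adjusted p = 0.0532 with an estimated correlation). The other lists that passed in HET or KO ageing did so only with the preset correlation. Without the libraries with S100a9 above 5000 TPM, the monocyte and T and NK cell lists no longer passed in KO (adjusted p = 0.140 and 0.135). Adjusted over the list alone, HET and KO had 34 and 38 interferon-stimulated, 20 and 17 disease-associated and 9 and 7 monocyte rises, and 24 and 15 homeostatic falls.

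Whether young Tbk1-deficient microglia carried an aged-like profile, which the series title names, was tested with ageing scores. With the HET ageing genes, which share no library with the groups compared, the score was -2.87 ± 0.0989 (SD, n = 5) in KO and -3.26 ± 0.137 (n = 6) in WT at 4 months. The difference of 0.390 (exact permutation p = 0.00433, 462 permutations) was 29.3% of the ageing difference in HET, and 5 of 5 KO libraries lay above the highest WT library. With the KO ageing genes, a score added after the data were seen, HET lay above WT by 0.350 (exact permutation p = 0.00433), 31.7% of the ageing difference in KO. After removing the within-group slope on genes detected per library, 0.0293 of this HET difference was left (8.37%, exact permutation p = 0.284), and 0.331 of the KO difference (84.9%, exact permutation p = 0.0130). With the WT ageing genes, KO did not lie above HET: the scores were -2.97 ± 0.0905 and -2.85 ± 0.218 (n = 5 each), a difference of -0.11 (exact permutation p = 0.349, 252 permutations). The sign turned without the libraries with S100a9 above 5000 TPM, a score built from fewer ageing genes (0.198, exact permutation p = 0.0159). The rising HET ageing genes as a set were higher in KO than in WT (camera p = 7.3e-05 with an estimated correlation) and the falling ones lower only with the preset correlation (p = 1.7e-14, p = 0.0918 with an estimated correlation).

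Of the 136 genes that rose in KO against WT at 4 months, 99 also rose in WT ageing (18.4 in independent lists) and 0 fell. Of the 23 that fell, 9 also fell (1.35) and 3 rose. These comparisons share the 6 young WT libraries, and part of the excess may come from them. The fold changes correlated at r = 0.459 across genes, against a mean of 0.502 and a highest value of 0.711 in 100 simulations of unchanged groups with shared controls. The covariance was 0.0451 against a simulated 0.0229. The simulated groups drew on deviations of all libraries of both ages, whose spread need not match that of the young WT libraries. The simulated values may therefore overstate or understate the part that shared controls add. With the controls split over 20 splits, mean r was 0.231 (0.154 to 0.306) and the covariance 0.0271. Against ageing in HET, with no shared library, 89 of the 136 rises were shared (6.69 in independent lists) and r was 0.320. Of the 106 rises in KO against HET, 58 rose in WT ageing (14.3) and 3 fell, while of the 55 falls 2 fell (3.23) and 22 rose, and r over all genes was -0.05.

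**Figure D5:**
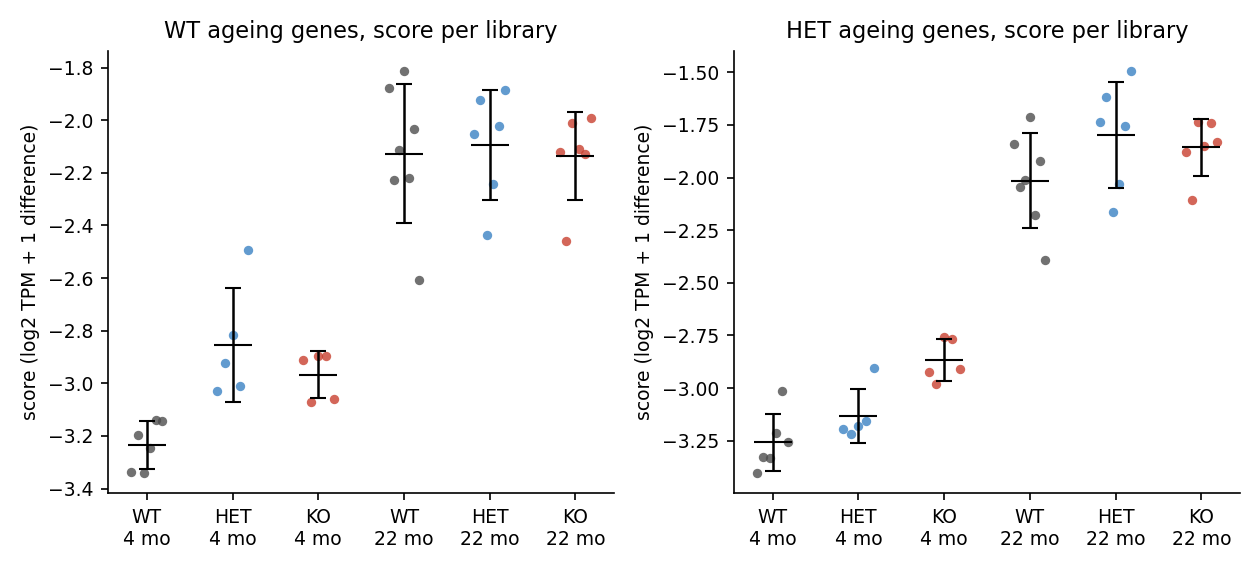
Ageing scores (log2 units, y axis) of each library by group, from genes called in ageing of WT and of HET, with group means and SDs. With the HET ageing genes the 4-month means were -3.26 in WT, -3.13 in HET and -2.87 in KO, and the 22-month means lay between -2.01 and -1.80.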

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

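The tests of genes detected per library, of correlated macrophage markers and of other splits of the samples were set before their results were seen; the other tests here, and the 1 Mb window around Cx3cr1, were chosen after. Samples far from the others of their group were found in 29 of 342 groups tested, and chance gives about 1 in 20.

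Slc25a38 and Rpsa, both beside Cx3cr1, were higher in HET and in KO than in WT at both ages. A change graded with the Tbk1 alleles lost is argued against: over both genes and ages KO minus HET was -0.0479 (upper 95% bound 0.0718) where HET minus WT was 0.716. A chromosome segment carried with the Cre cannot be told apart from an effect of losing the first Tbk1 allele, since every HET and KO mouse carried both and KO also lay above WT (0.668, upper 95% bound 0.775). Without Slc25a38 and Rpsa, 0 of 26 genes within 1 Mb of Cx3cr1, itself among them, were called in HET against 5 of 15009 elsewhere (Fisher's exact test, two-sided, p = 1), which decides neither, since a segment need not change each gene in it. The largest HET difference among the 26, chosen after its values were seen, was in Gm33858, which overlaps Cx3cr1. It stood at log2 1.16 (limma adjusted p = 0.212) at 4 months and 0.70 (adjusted p = 0.876) at 22 months. The Cre itself, absent from WT, stays open as well.

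The ageing score was higher in KO (scored with the HET ageing genes) and in HET (scored with the KO ageing genes) than in WT at 4 months. For KO, 0.331 (84.9%, exact permutation p = 0.0130) of the difference was left after removing the slope on genes detected and 0.353 (90.6%, exact p = 0.00216) after removing that on neutrophil RNA, which argues against either as the whole cause. For HET, 0.332 (94.8%, exact p = 0.00866) was left after neutrophil RNA but 0.0293 (8.37%, exact p = 0.284) after genes detected. The HET difference may thus come from the number of genes detected. That number was counted from the same TPM values, so a real rise of low ageing genes past a TPM of 1 would raise it too. Removing its slope may then remove a real difference, and the test cannot separate the 2. Within groups, genes detected correlated at r = 0.665 with the score used for KO and at 0.929 with that used for HET. At 4 months the mean number of genes detected was 13073 in WT, 13549 in HET and 13193 in KO. HET thus lay further above WT than KO did, and the slope had more to remove. The unlike outcomes follow at least in part from this, and the genes scored differed as well. An effect of the second Tbk1 allele cannot be told apart from none, since KO minus HET was -0.11 with all WT ageing genes and 0.117 (exact p = 0.524) with those changed over 2-fold. Without the libraries with S100a9 above 5000 TPM, which takes out HET replicate 5 at 4 months and 4 of 7 aged WT libraries, it was 0.198 (exact p = 0.0159), and without HET replicate 5 alone -0.0284 (exact p = 0.698). The Cre, absent from WT, stays open.

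Border-associated macrophage markers were lower in KO than in WT at 22 months. A fall shared with the blood cell types tested is argued against. The macrophage score fell further than the mean score of monocyte, neutrophil, T, NK and B cell markers, by a difference of -1.13 (exact permutation p = 0.0431). KO minus WT of that mean score was 0.0549. Fewer such macrophages among the sorted cells, which the CD11b and CD45 sort would not fully remove, stays open. The markers varied together within groups (mean pairwise r 0.305, 95th percentile of 10000 random lists 0.0860). That test used deviations from the group means, so it does not tell why KO lay below WT. A graded effect of Tbk1 also stays open at 22 months, since HET minus WT was -0.53 (exact p = 0.0478, 1716 permutations) and KO minus WT -1.07 (exact p = 0.00175). Both differences from WT also follow the Cre. At 4 months the mean macrophage score was 2.76 ± 0.328 (SD) in WT, 2.97 ± 0.189 in HET and 2.30 ± 0.388 in KO. That order did not follow the number of alleles lost. Lower expression in unchanged numbers of macrophages was not tested.

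In 100 splits of the same libraries, the real one included, no other split called as many genes for KO against WT at 4 months (1 split as large, 159 genes called, highest other 128) and at 22 months (1 split, 185 called, highest other 55). The same held for KO against HET at 4 months (1 split, 161 called, highest other 8) and 22 months (1 split, 102 called, highest other 18) and for HET against WT at 4 months (1 split, 5 called, highest other 2). It held for ageing in WT (1 split, 2982 called, highest other 964), HET (1 split, 1141 called, highest other 736) and KO (1 split, 2102 called, highest other 509). With 100 splits per comparison, 1 is the lowest count possible, so these results make chance less likely without excluding it. The count of 5 in HET against WT at 4 months itself fell to 2 in fits that left out 1 library. For HET against WT at 22 months, 9 splits gave at least the 6 genes called and 1 gave 425, several times the real count, which points to some structure among these libraries. Which libraries that split set apart, and why, was not tested. With 0 genes called in each interaction, all 100 splits necessarily called at least as many, which says nothing about chance. The highest other splits called 1 gene for KO and 247 for HET, the latter also pointing to some structure, whose source was not tested.

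Several libraries lay apart from the others of their group in marker genes. The library with the fewest genes at a TPM of 1 in aged WT was replicate 7 (13344, nearest 13811). Cx3cr1 was lowest in aged KO replicate 1 (3132 TPM, nearest 3508), and Xist highest in young KO replicate 1 (13.2, nearest 9.58) and aged KO replicate 1 (29.7, nearest 22.1). S100a9 was highest in young WT replicate 5 (4913 TPM, nearest 1635) and young HET replicate 5 (5273, nearest 1520).

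Genes named in the comparisons also had single high libraries. In young KO replicate 5, Il2rg (134 TPM, nearest 85.4), H2-K1 (2110.3, nearest 1499) and Cxcl16 (238, nearest 185) were highest. Cxcl16 was highest in aged KO replicate 2 (301, nearest 249), Cxcl13 in aged WT replicate 4 (42.8, nearest 22.0), Axl in aged WT replicate 3 (124, nearest 96.6) and Il12b in aged WT replicate 7 (1.62, nearest 0.290) and aged HET replicate 5 (0.687, nearest 0.235). In young WT replicate 6, Spp1 (11.9, nearest 5.11) and Ch25h (4.54, nearest 1.73) were highest.

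Scores, as mean log2(TPM + 1), set other libraries apart. The WT ageing score was lowest in aged KO replicate 2 (-2.46, nearest -2.13). Young HET replicate 5 had the highest HET ageing score (-2.91, nearest -3.16), KO ageing score (-2.72, nearest -3.10) and cell death score (5.13, nearest 5.03) and the lowest autophagy score (5.48, nearest 5.59). Young KO replicate 5 was highest for MHC class I (7.72, nearest 7.34) and class II genes (7.32, nearest 7.05). Glycolysis was lowest in young KO replicate 4 (6.51, nearest 6.63) and highest in aged WT replicate 6 (7.08, nearest 6.82), and complement lowest in young WT replicate 2 (8.58, nearest 8.71). B cell markers were highest in young WT replicate 3 (4.30, nearest 3.43), and erythroid markers in young HET replicate 4 (2.17, others 0) and young KO replicate 4 (5.74, nearest 0.849).

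The KO effect differed between ages for 13 lists in camera with the preset correlation. The disease-associated list (median -0.37, adjusted p = 9.4e-13, adjusted p = 0.0330 with an estimated correlation) held with an estimated correlation and the other 12 did not. Lower at 22 than at 4 months were interferon-stimulated (median -0.21, adjusted p = 4.0e-08), NF-kB (median -0.07, adjusted p = 0.00443), MHC class I (median -0.10, adjusted p = 1.5e-04), MHC class II (median -0.11, adjusted p = 0.00137), proliferation (median -0.32, adjusted p = 9.2e-06), lipid efflux (median -0.07, adjusted p = 0.00141), glycolysis (median -0.08, adjusted p = 0.0211), complement (median -0.08, adjusted p = 0.0136), border-associated macrophage (median -0.50, adjusted p = 2.5e-06) and monocyte lists (median -0.46, adjusted p = 0.0211). Their adjusted p values with an estimated correlation were 0.270, 0.270, 0.270, 0.270, 0.270, 0.136, 0.623, 0.364, 0.136 and 0.678. Homeostatic (median 0.12, adjusted p = 6.6e-04, adjusted p = 0.523 with an estimated correlation) and erythroid lists (median 3.01, adjusted p = 9.3e-04, adjusted p = 0.270 with an estimated correlation) were higher. The HET effect differed for lysosome (median 0.06, adjusted p = 0.0174, adjusted p = 0.886 with an estimated correlation), macrophage (median -0.73, adjusted p = 1.6e-06, adjusted p = 0.145 with an estimated correlation) and erythroid lists (median 3.67, adjusted p = 2.6e-06, adjusted p = 0.145 with an estimated correlation).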

How the results depend on the processing

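The planned settings were fixed before the data were examined; the neutrophil covariate, the exclusion of libraries with S100a9 above 5000 TPM and the list tests with the dissociation covariate were chosen after seeing the data. Quantile normalization ended 6 and added 10 of the list calls, median-of-ratios scaling ended 3 and added 4, and a pseudocount of 0.1 ended 1 and added 2, of 308 list tests with 105 calls, and none of these 3 turned the direction of a list. With an estimated correlation 82 of the 105 list calls were lost. Of 393 calls among 725 named gene values, 90 ended without the libraries with S100a9 above 5000 TPM, 74 with the dissociation covariate, 52 without a filter, 42 in fits on the groups compared only, 31 with quantile normalization, 16 with median-of-ratios scaling, 12 with the replicate block, 6 with a pseudocount of 0.1, 3 with library quality weights and 1 with the neutrophil covariate. A mean TPM of at least 5 ended 0 of 351. Unknown depth leaves the counting error of low genes unmeasured.

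Without a filter, 99 genes were called in KO against HET at 4 months and 1346 in ageing in KO, with more genes tested, and Tbk1 in HET against WT (-0.61 and -0.55) no longer passed. In fits on the groups compared only, with fewer libraries behind the spread, HET against WT at 4 months gave 1 gene, KO against HET at 4 months 55 and ageing in HET 593, and Tbk1 in HET at 4 months (-0.61) no longer passed. Library quality weights gave 282 genes in KO against WT at 4 months, 1910 in ageing in HET and 3 in the KO interaction; the cause was not tested. The dissociation covariate gave 1382, 374 and 735 genes in ageing in WT, HET and KO, and turned the lysosome and immediate early lists in ageing in HET (adjusted p = 0.661 for each), with 3 list calls ended and 11 added. The covariate is the score of the immediate early list, so it removes that list's own change; the cause of the others was not tested. The neutrophil covariate gave 1 gene in the KO interaction, and ended 1 list call and added 3. The cause was not tested. With this covariate 230 genes were called in KO against WT and 134 in KO against HET at 22 months, and 2822 in ageing in WT. Quantile normalization turned the sign of Cst3 in ageing in KO, at 7.11e-15 log2, in effect 0.

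The limit of 5000 TPM for S100a9 took out 4 of 7 WT, 2 of 6 HET and 3 of 6 KO libraries at 22 months. It took out 1 of 5 HET libraries at 4 months. Without these libraries, 84 genes were called in KO against WT at 22 months and 3 in HET against WT at 4 months. KO against HET gave 101 and 31 at 4 and 22 months, ageing in WT 671 and the HET interaction 1. The loss of libraries was not separated from an effect of neutrophil RNA. Tbk1 no longer passed in HET against WT (-0.53) and KO against HET (-0.52) at 22 months. The difference in the WT ageing score between KO and HET at 4 months turned to 0.198 (exact permutation p = 0.0159). Of the list calls 10 ended and 33 were added, and 12 list tests turned direction. Those that turned, with their adjusted p, were lysosome in KO against WT at 22 months (0.919), glycolysis in KO against HET at 22 months (0.00280), proliferation in ageing in KO (0.00156), and B cells in HET against WT at 22 months (7.1e-04). In the HET interaction, MHC class I, proliferation and complement (0.0282 each) and lysosome (0.170) turned. The cause was not tested. Neutrophils also turned, in HET against WT at 22 months (2.7e-04), ageing in WT (4.6e-08) and HET (0.0259) and the HET interaction (4.0e-04), which says nothing, since libraries were left out by a neutrophil transcript.

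Leaving out 1 library at a time gave 113 (without KO replicate 5) to 168 genes in KO against WT at 4 months and 144 to 202 at 22 months, 2 to 7 and 5 to 6 in HET against WT, and 77 (without KO replicate 5) to 257 (without KO replicate 1) and 68 to 111 in KO against HET. Ageing gave 2178 to 3631 genes in WT, 754 (without replicate 1 at 4 months) to 1567 (without replicate 5 at 4 months) in HET and 1351 (without replicate 6 at 22 months) to 2477 in KO. The interactions gave 0 to 3 genes for KO (3 without replicate 4 at 4 months) and 0 to 1 for HET (1 without replicate 5 at 22 months). Tbk1 in HET against WT lay between -0.70 and -0.54 at 4 months and between -0.58 and -0.51 at 22 months. Ageing score differences lay between -0.16 and -0.03 (KO against HET, WT ageing genes), 0.365 and 0.439 (KO against WT) and 0.260 and 0.392 (HET against WT). The replicate numbers did not pair the samples: same-numbered libraries had a mean correlation of deviations of 0.0108, with 15 of 81 pairs over 0.1. A fit with the replicate block called 161 and 171 genes in KO against WT at 4 and 22 months, 5 and 6 in HET against WT, 140 and 85 in KO against HET, 3447, 997 and 1666 in ageing and 0 in the interactions.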

Other observations

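Of the proliferation genes, 7 of 23 rose with age in WT, and the list passed only with the preset correlation (median log2 0.54, adjusted p = 5.8e-04, adjusted p = 0.363 with an estimated correlation, adjusted p = 0.522 without the libraries with S100a9 above 5000 TPM). Among the members that rose were the replication licensing factor Mcm2 (0.75, SE 0.16, adjusted p = 0.0017) and Cenpf (0.84, SE 0.20, adjusted p = 0.0032). Immediate early genes did not pass as a list (median 0.33, adjusted p = 0.127), while Egr2 (1.45, SE 0.22, adjusted p = 1.2e-05) and Nr4a1 (1.54, SE 0.27, adjusted p = 1.4e-04) rose in 7 of 7 aged libraries against the young median. With quantile normalization the immediate early list passed camera as higher (adjusted p = 0.0119). In the TBK1-STING-TLR list 5 of 22 members rose and 3 fell (median 0.06, tested direction lower, adjusted p = 0.764). Ikbke, a kinase related to Tbk1, rose by 1.26 (SE 0.27, adjusted p = 0.0013) and Tank by 0.55 (SE 0.09). The senescence gene Cdkn1a rose by 1.14 (SE 0.11, adjusted p = 2.7e-09) and Gdf15 by 1.196 (SE 0.24), and the list did not pass (median 0.21, adjusted p = 0.266).

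The remaining ageing lists in WT did not pass: RIPK1 and cell death (6 of 21 higher, 2 lower, median 0.17, adjusted p = 0.560), cholesterol synthesis (4 of 18 higher, 1 lower, median 0.19, adjusted p = 0.203), glycolysis (2 of 16 higher, median 0.10, adjusted p = 0.280), oxidative phosphorylation (4 of 23 higher, 2 lower, median 0.15, adjusted p = 0.736) and complement (4 of 22 higher, 2 lower, median -0.02, mean 0.24, adjusted p = 0.730). Markers of B cells (1 of 6 higher, 1 lower, adjusted p = 0.736), astrocytes (1 of 4 higher, adjusted p = 0.498), oligodendrocytes (0 of 5 called, adjusted p = 0.434), endothelial cells (1 of 5 higher, 1 lower, adjusted p = 0.736) and erythroid cells (0 of 4 called, median -1.49, adjusted p = 0.103) did not pass either. The complement gene C3 rose by 1.85 (SE 0.36).

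Xist, which is expressed from the inactive X chromosome, stood at 0.022 TPM in aged WT replicate 6, and between 13.2 and 23.9 TPM in the other aged WT libraries. Tsix stood at 0.202 TPM in this library. The Y chromosome gene Ddx3y stood at 0 TPM, which goes against a male mouse. The cause of the low Xist was not tested. Without this library 162 genes were called in KO against WT at 22 months and 2667 in ageing in WT.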
